A study of Mus musculus with 9 samples.

How the data were processed

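Cytotoxic T lymphocytes (CTL) were made from spleens of mice with the P14 T cell receptor transgene, whose CD8 T cells recognise a peptide of lymphocytic choriomeningitis virus. Splenocytes were activated with the peptide, interleukin 2 and interleukin 12 for 48 h and cultured for 96 h more, 6 days in all. During the last 48 h the cells received the solvent DMSO, rapamycin at 20 nM, or KU-0063794 at 1 uM. Total RNA of each of the 9 cultures was measured on 1 Affymetrix mouse expression array. Each group held 3 arrays, and arrays with the same replicate number came from cells of the same spleen.

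The deposited values were log2 signals per probe set, 1 column per array. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.3.1; the methods of background correction, summarisation and normalization were not given in the sources used here. The log2 scale was checked on the hybridisation controls bioB, bioC, bioD and cre, whose values rose by 0.932 per doubling of the nominal concentration and spanned 5.92, against 6.06 for log2 and 4.20 for natural logarithms of the nominal concentrations. Array medians lay between 0.47 and 0.53 log2, so the deposited values were already normalized between arrays, and they were used as deposited. No 2 arrays had identical columns, and no column of values was left unused.

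The table held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 carried a single gene symbol in the array annotation and were used. A further 932 carried several symbols and 9160 were not listed in the annotation, and neither kind was analysed here by gene. Some genes of the lists had no probe set in the annotation and are not reported here. Each of 18193 genes was represented by its probe set with the highest mean log2 signal over the 9 arrays, and genes were tested when that mean was above the 40th percentile of all probe sets other than controls (0.31 log2), which left 13278 genes. The annotation gave symbols and gene identifiers without genomic positions. Background was gauged by 32 genes restricted to tissues such as liver, pancreas, heart, brain, kidney and testis, whose median signal was 0.36 log2 and whose 95th percentile, 1.23 log2, is called the background level. Of the genes tested, 8415 lay above it.

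Group differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with the 3 groups as fixed effects over all 9 arrays and two-sided moderated tests. Benjamini-Hochberg adjustment covered the 13278 genes of each contrast, with a threshold of 0.05, and genes were counted again at a log2 fold change of at least 1 in either direction. The 3 contrasts were rapamycin against DMSO, KU-0063794 against DMSO and KU-0063794 against rapamycin. The main fit, fixed before the data were seen, carried no term for the spleen, although arrays of one number came from one spleen. This leaves the spread between spleens in its error, so genes that did not pass in it may pass with a block. A fit with the spleen as a fixed block was set beside it. Whether the numbers pair the arrays was checked on the deviations of each array from its group mean: in all 9 pairings of arrays with the same number the deviations correlated across genes (r 0.345 to 0.533), and in the 18 pairings with different numbers r was -0.414 to -0.0791.

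The design fixed 31 gene lists. Those with at least 5 tested members, other than the background list, were 28, and they were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast. Member counts are given for the test adjusted over all genes and, where named, for the test adjusted over the list alone. Most genes named in the text came from a rule with 3 parts. The first took the 10 highest and 10 lowest log2 fold changes past the threshold with the same sign in all 3 spleens. The second took up to 4 members of each list past the threshold, 2 in each direction. The third was a fixed panel of T cell and metabolic genes; the text prints a part of all these. Groups, tests, lists and this rule were set before the data were examined. The shared response was the set of genes called in both contrasts against DMSO in the same direction. Because both contrasts use the same 3 DMSO arrays, the correlation and covariance of their fold changes were set beside 100 simulations of unchanged groups against shared controls.

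Other settings fixed beforehand covered the spleen as a fixed or random block, fits of only the 2 groups compared, quantile normalization and median centring, no filter or stricter filters, other ways to take probe sets, trend, robust and array-weighted fits, every array and every spleen left out in turn, and for the lists an estimated inter-gene correlation, fry, the spleen block and no filter. Added after the data were seen were set tests with the spleen block, set tests without each array or spleen, and the spleen block with arrays left out. The procedure was tested on simulated data, with 200 changed genes in each of 20 simulations at the spread of these arrays. For rapamycin the fit without a block recovered 50.4% of log2 changes of 0.5 and 94.0% of changes of 1. For KU-0063794 it recovered 48.2% and 95.1%. With the spleen as a block 81.0% and 77.5% of changes of 0.5 were recovered for the 2 drugs. Of the calls 4.84% and 4.94% were false with the block, against 0.342% and 0.426% without it. In these simulations arrays of one spleen shared 0.5 of the variance and genes were drawn independently. The consensus correlation of arrays of one spleen in these data was 0.254. The gain from the block and the low share of false calls without it depend on this setting and may differ in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

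For arrays no depth is defined; the number of arrays limits the precision. The median half-width of the 95% confidence interval of a log2 fold change was 0.25 without and 0.21 with the spleen block.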

Results

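Gene expression was measured in 9 cultures of mouse P14 cytotoxic T lymphocytes on day 6 of culture, 3 with DMSO, 3 with rapamycin and 3 with KU-0063794, each inhibitor being present for the last 2 days. Rapamycin binds FKBP12 and inhibits mainly mTOR complex 1, whereas KU-0063794 inhibits the mTOR kinase itself and so both mTOR complexes. Between 31.6% and 32.3% of probe sets lay above the background level on each array, and array medians were 0.47 to 0.53 log2. The 3' minus 5' signal of the actin control was 0.49 to 0.65 log2 in DMSO, 0.62 to 0.72 in rapamycin and 0.65 to 0.70 in KU-0063794 cultures, higher with each inhibitor in all 3 spleens, and that of the Gapdh control, between -0.25 and 0.04, was lower in all 3. Signals correlated across probe sets with r between 0.987 and 0.996 for every pair of arrays; probe sets are not independent replicates. The T cell receptor and CD8 genes of the CD8 T cell identity list were all above the background level in DMSO cultures, 13 of 13, with a median of 7.23 log2. Of genes listed as markers of other cells, 3 of 11 for B cells and 3 of 6 for CD4 T cells were above it. The counts were 1 of 15 for myeloid cells, 1 of 4 for NK cells and 2 of 9 for erythroid or stromal cells. Those above it included Ighm (8.03 log2), Tnfrsf18 (7.59 log2) and Klrc1 (5.04 log2). Cd79a (0.76 log2), Pax5 (0.49 log2), Cd4 (1.10 log2), Foxp3 (0.12 log2) and Ncr1 (0.57 log2) were among those below the background level. Which cells gave the 3 high signals was not tested. The array's control probe set for the B1 repeat, a short interspersed element, read 8.20 ± 0.39 log2 (SD, n = 3) in DMSO, 7.13 ± 0.38 in rapamycin and 7.39 ± 0.33 in KU-0063794 cultures. Its adjusted p from limma was 0.0589 for rapamycin and 0.149 for KU-0063794, and 0.00143 and 0.00234 with the spleen as a block.

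The comparison of rapamycin with DMSO asked which transcripts of established CTL depend on signalling that rapamycin blocks. With rapamycin 4 granzyme genes, Ifng, 12 of 27 ATF4 targets, 5 of 20 sterol synthesis genes and 4 of 19 glycolysis genes fell, and 18 of 24 mitosis and 6 of 26 DNA replication genes rose. These 5 lists were called by camera (adjusted p = 0.219 with an estimated correlation for each). The granzyme gene Gzmg read 5.87 ± 1.35 log2 (SD, n = 3) in DMSO and 1.12 ± 0.69 in rapamycin cultures, the latter above the background level on 1 of 3 arrays (log2 fold change -4.75, SE 0.58, adjusted p = 0.00649). As the rapamycin mean lay below that level of 1.23 log2, the size of this fall is uncertain. Ifng, which encodes interferon gamma, fell from 9.86 ± 0.59 to 7.25 ± 0.61 log2 (log2 fold change -2.62, SE 0.39, adjusted p = 0.0105). Asns, which encodes asparagine synthetase, fell from 7.23 ± 0.17 to 6.02 ± 0.15 log2 (log2 fold change -1.22, SE 0.12, adjusted p = 0.00439), and each of these 3 genes was lower in all 3 spleens.

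Genes of amino acid supply were among those that fell. Of 27 measured targets of ATF4, the transcription factor that induces amino acid synthesis, transport and tRNA charging genes, 12 fell, none rose and 15 did not pass, and 21 fell when adjusted over the list alone; the list median was -0.51 log2 (camera adjusted p = 2.01e-18). Besides Asns these included Psph (log2 fold change -1.23), which encodes the last enzyme of serine synthesis, and Psat1 (-0.44). Trib3 (-1.20) and Atf4 itself (-0.70), which the naming rule did not take for rapamycin, fell as well. Slc7a3, a transporter of arginine and lysine outside the list, fell by 2.49 on the log2 scale and Smox, the spermine oxidase gene, fell by 1.83. Of 20 sterol synthesis genes 5 fell, or 15 when adjusted over the list alone, with Tm7sf2 at -0.89 and Mvd, the mevalonate diphosphate decarboxylase gene, at -0.74 (list median -0.49, camera adjusted p = 1.42e-11). Of 19 glycolysis genes 4 fell, or 14 when adjusted over the list alone (median -0.39, camera adjusted p = 5.41e-09). They were Aldoc (-1.11), Pgam1 (-0.60), Pfkp (-0.58, with 1 of its 3 probe sets going the other way) and the lactate transporter gene Slc16a3, which lay below the background level in both groups. Hk2 and Slc2a1, which encode hexokinase 2 and the glucose transporter GLUT1, both had a log2 fold change of -0.71 and passed with the spleen as a block (adjusted p = 0.0522 and 0.138 without it, 0.00904 and 0.00314 with it). Hk2 also passed after quantile normalization (adjusted p = 0.0414) and without rapamycin replicate 2 (0.0429) or KU-0063794 replicate 2 (0.0337). Of 23 hypoxia response genes 3 fell, or 10 when adjusted over the list alone, and 1 rose (median -0.44, camera adjusted p = 6.45e-07): Ero1a (-1.24), Ak4 (-1.13, with 2 of its 4 probe sets going the other way) and Ddit4 (-1.08) fell, and Kdm3a (0.70), a histone demethylase gene, rose. With an estimated correlation the adjusted p was 0.219 for the ATF4, sterol and glycolysis lists and 0.272 for the hypoxia list.

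Of 15 fatty acid synthesis genes 2 fell, the desaturase gene Scd1 (-1.78) and Acss2 (at least 1.86-fold lower, since its rapamycin arrays were at background). The list was called at a camera adjusted p of 0.0107 (adjusted p = 0.265 with an estimated correlation), and not without rapamycin replicate 3 (adjusted p = 0.0722) or spleen 2 (0.0608). No member of the 27 oxidative phosphorylation genes (median -0.10) or the 20 unfolded protein response genes (median -0.14) passed singly, against 1 and 2 lower with the spleen as a block. Both lists were called downward (camera adjusted p = 0.0146 and 0.0258), each with adjusted p = 0.272 with an estimated correlation. The first call was lost without rapamycin replicate 1 (adjusted p = 0.0601), and the second without DMSO replicate 3 (0.111), rapamycin replicate 1 (0.0682), rapamycin replicate 2 (0.0699) or spleen 2 (0.0825). Of 21 cytosolic ribosomal protein genes only Rps6 rose (0.52), and the list was called upward with a median of 0.10 (camera adjusted p = 0.000758, adjusted p = 0.219 with an estimated correlation). The pentose phosphate list, with Rpia at -0.44 past the test, the purine and one-carbon list, with Paics at 0.41, and the ribosome biogenesis list, with no member past it (2 with the block), were not called (camera adjusted p = 0.680, 0.156 and 0.616). With the block 2 genes rose and 2 fell in each of the first 2. The purine list was called without DMSO replicate 2 (adjusted p = 0.0357).

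Among effector molecules, 4 of 23 cytotoxic granule genes fell and 2 rose, against 8 and 3 with the spleen as a block. Those that fell without the block were Gzmg, Gzmd (-3.60), Gzme (-2.96) and Gzmf (-2.69), neighbouring granzyme genes whose sequences are very similar. Cross-hybridisation between their probe sets was not tested. Lamp1 (0.48) and Lamp2 (0.39), which encode lysosomal membrane proteins, rose, although 2 of 4 Lamp2 probe sets went the other way. Granzyme B and perforin, the main killing molecules of CTL, did not pass. Gzmb read 12.33 ± 0.06 log2 in DMSO and 12.08 ± 0.08 in rapamycin cultures (adjusted p = 0.127, or 0.0434 with the spleen as a block), close to the highest signals of the arrays, 12.19 to 12.38 log2, and its DMSO values were the highest of their arrays. Prf1 had a log2 fold change of -1.49 with an SE of 0.73 (adjusted p = 0.334, or 0.00393 with the block), and 1 of its 2 probe sets went the other way. The granule list was not called (camera adjusted p = 0.0949) except with the block (0.00653, but adjusted p = 0.354 with an estimated correlation), without DMSO replicate 2 (0.00672), rapamycin replicate 1 (0.0171) or spleen 1 (0.0160). Of 15 cytokine and chemokine genes 3 fell, Ifng, Ccl4 (-1.31) and the lymphotoxin gene Lta (-0.76), and Ccl5 (0.76) rose. That list was called downward (camera adjusted p = 0.0350, adjusted p = 0.219 with an estimated correlation), but not without rapamycin replicate 1 (0.0601), rapamycin replicate 2 (0.0979) or spleen 2 (0.149).

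Cell division genes went the other way. Of 24 mitosis genes 18 rose, none fell and 6 did not pass, and 23 rose when adjusted over the list alone (median 0.57, camera adjusted p = 3.17e-23). Cenpf, a kinetochore protein gene, had a log2 fold change of 1.11, the mitotic kinesin gene Kif20a 0.96 (SE 0.14, adjusted p = 0.010), Ccna2 0.49 and Bub1 0.45. Aspm (1.09) and E2f7 (1.11), outside the list, were among the 10 highest changes. Of 26 DNA replication genes 6 rose, or 12 when adjusted over the list alone, among them Uhrf1 (0.66) and the helicase genes Mcm7 (0.62) and Mcm6 (0.51) (list median 0.28, camera adjusted p = 1.15e-09). With an estimated correlation the adjusted p was 0.219 for both lists.

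Few genes of trafficking and differentiation passed. None of 15 naive and memory T cell genes passed, against 2 higher with the spleen as a block (list camera adjusted p = 0.156, or 0.0496 with the block and 0.190 with an estimated correlation as well). Ccr7, a lymph node homing receptor gene, had a log2 fold change of 0.93 (adjusted p = 0.0776, or 0.00585 with the block and 0.0485 without DMSO replicate 2), and Klf2, S1pr1, Il7r and Eomes passed in neither fit. Of 25 effector and inhibitory receptor genes Pdcd1 fell (-0.92), or 5 with the block, and Tbx21 did not pass; the list was called with the block (camera adjusted p = 0.114 without it, 0.0278 with it, but adjusted p = 0.365 with an estimated correlation as well). FOXO target genes Ccng2 (1.04) and Klhl24 (1.60) rose, 2 of 20. In the list of PI3K and mTOR pathway genes Pdcd4 (0.82), which encodes a translation inhibitor, rose, and Eif4ebp1 (-1.01) and Sgk1 (-0.65) fell, 3 of 27. Il1r2 (-1.55), the decoy receptor gene for interleukin 1, and Tgfbr2 (-0.66) fell among 21 cytokine receptor genes. In the interferon response list of 19, Gbp2 (1.42) rose and Mx1, above the background level on 1 of 3 rapamycin arrays, fell. In the lysosome and autophagy list of 27, Npc2 (0.65) rose and Ctsd (-0.75) fell. Cdkn1a (-0.77) and Hmox1 (-0.73) fell among 14 apoptosis and p53 target genes, and the integrin gene Itgav (-0.69) among 19 chemokine receptor and adhesion genes. These lists were not called (camera adjusted p from 0.0949 to 0.796), except the apoptosis list without DMSO replicate 1 (0.0319), rapamycin replicate 3 (0.0428) or spleen 1 (0.0338). With the block 4 genes rose and 2 fell in the FOXO list and in the lysosome list, and 3 rose and 4 fell in the chemokine receptor list. None of 13 CD8 identity, 8 B cell and 5 CD4 T cell markers passed, although with the block 3 CD8 identity genes rose and 1 fell and 1 CD4 T cell marker fell. Of 7 myeloid markers Cd68 passed while below the background level in both groups; none of these lists was called (camera adjusted p from 0.504 to 0.926).

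In all, 590 of 13278 genes differed between rapamycin and DMSO at an adjusted p under 0.05 in limma, 352 higher and 238 lower, and 63 of them by at least 2-fold, 16 higher and 47 lower. The count at 2-fold was 93 with the spleen as a block, 27 without DMSO replicate 1, 41 without rapamycin replicate 1 and 29 without rapamycin replicate 3. With the spleen as a block 1561 genes differed, 828 higher and 733 lower, and all 590 were among them. The count of all genes called was 197 without DMSO replicate 1, 368 without DMSO replicate 3, 227, 326 and 168 without rapamycin replicates 1, 2 and 3, and 388 without KU-0063794 replicate 1. Of the 66 genes past the test that the naming rule took, 47 lost their call without at least 1 array and 19 kept it throughout, among them Gzmg, Ifng, Asns, Psph, Slc7a3, Smox, Kif20a, Aspm, Gbp2, Klhl24, Pdcd1 and Lta. Over the 9 left-out arrays 8 to 18 mitosis genes, 4 to 12 ATF4 targets, 1 to 5 sterol genes, 0 to 4 glycolysis genes and 0 to 5 DNA replication genes passed, each count being lowest without rapamycin replicate 3.

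**Figure D1:**
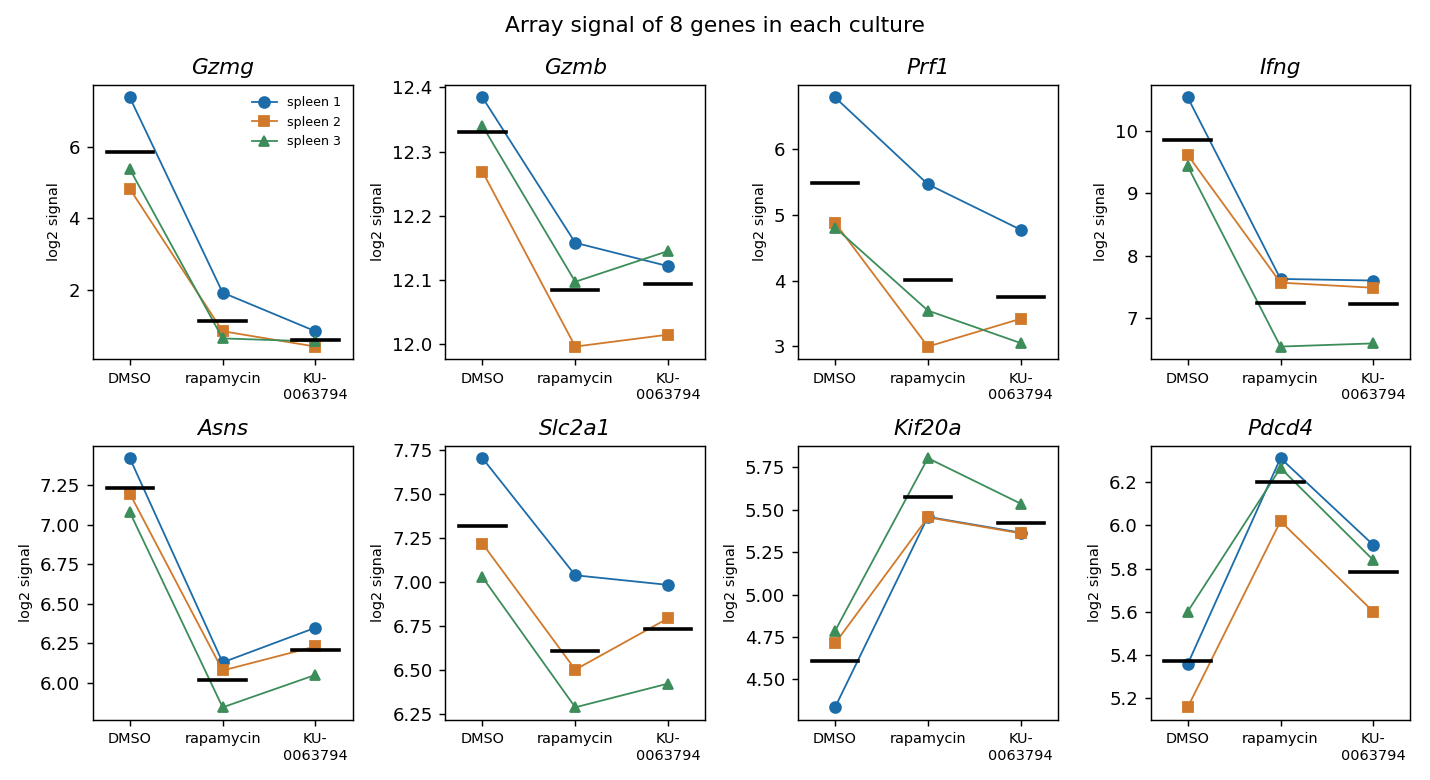
Log2 signal of 8 genes on each of the 9 arrays, by treatment; each panel has its own vertical range, lines join cultures of the same spleen and black bars are group means (n = 3). Gzmg falls from a mean of 5.87 with DMSO to 1.12 with rapamycin and 0.59 with KU-0063794, and Gzmb, near the top of the array scale, has means of 12.33, 12.08 and 12.09.

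The comparison of KU-0063794 with DMSO asked the same question for an inhibitor that acts on the mTOR kinase directly. The same 4 granzyme genes, Ifng, 12 of 27 ATF4 targets, 9 of 20 sterol synthesis genes and 3 of 19 glycolysis genes fell, and 17 of 24 mitosis and 6 of 26 DNA replication genes rose. These 5 lists were called by camera (adjusted p from 0.179 to 0.241 with an estimated correlation). Gzmg fell to 0.59 ± 0.22 log2 (SD, n = 3), at background on all 3 arrays, at least 24.9-fold below the DMSO mean (adjusted p = 0.00536). Ifng fell to 7.23 ± 0.55 log2 (log2 fold change -2.63, SE 0.39, adjusted p = 0.0114) and Asns to 6.21 ± 0.15 log2 (log2 fold change -1.02, SE 0.12, adjusted p = 0.00693). Kif20a rose from 4.61 ± 0.24 to 5.42 ± 0.10 log2 (log2 fold change 0.81, SE 0.14, adjusted p = 0.0177), and each of these 4 genes changed the same way in all 3 spleens.

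Of the 27 ATF4 targets 12 fell, or 22 when adjusted over the list alone (median -0.46, camera adjusted p = 1.20e-16), with Trib3 at -1.20, Ddit3 at -1.06, Gars at -0.39 and Psat1 at -0.37. Of the 20 sterol synthesis genes 9 fell, or 16 when adjusted over the list alone (median -0.62, camera adjusted p = 1.17e-15). Hmgcs1 (-0.99), the HMG-CoA synthase gene, Mvd (-0.99) and Nsdhl (-0.56) were among them, as was Sc5d (-0.57), for which 1 of 2 probe sets went the other way. Of the 19 glycolysis genes Aldoc (-1.52), Pfkp (-0.66) and Pgam1 (-0.61) fell, or 13 when adjusted over the list alone (median -0.40, camera adjusted p = 2.63e-09). Hk2 (-0.48, adjusted p = 0.174) and Slc2a1 (-0.58, adjusted p = 0.217) passed only with the spleen as a block (0.0363 and 0.00560). Of the 23 hypoxia response genes Ero1a (-1.35), Plod2 (-1.24) and Ddit4 (-1.02) fell and Kdm3a (0.63) rose, with 11 lower when adjusted over the list alone (median -0.49, camera adjusted p = 8.50e-06). With an estimated correlation the adjusted p was 0.179 for the ATF4 and sterol lists, 0.241 for glycolysis and 0.281 for hypoxia. Scd1 (-1.69) and Acss2 (at least 1.86-fold lower) fell among 15 fatty acid synthesis genes. That list was called (camera adjusted p = 0.0188, adjusted p = 0.281 with an estimated correlation), but not without DMSO replicate 2 (0.0977), KU-0063794 replicate 3 (0.0599) or spleen 2 (0.138).

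Of the 23 cytotoxic granule genes Gzmg, Gzmd (-4.36), Gzme (-3.50) and Gzmf (-2.95) fell and none rose, against 10 and 2 with the block, and the list was called downward (median -0.24, camera adjusted p = 0.00171, adjusted p = 0.373 with an estimated correlation). Gzmb (-0.24, adjusted p = 0.139) and Prf1 (-1.74, adjusted p = 0.244) passed only with the block (0.0482 and 0.00226); 1 of 2 Prf1 probe sets went the other way. Of 15 cytokine and chemokine genes Ifng, Ccl4 (-1.27) and Lta (-1.04) fell (median -0.33, camera adjusted p = 0.000365, adjusted p = 0.163 with an estimated correlation). Il1r2 (-1.45), Il12rb1 (-0.79), a subunit gene of the interleukin 12 receptor, and Tgfbr2 (-0.75) fell among 21 cytokine receptor genes. That list was called (camera adjusted p = 0.0115, adjusted p = 0.281 with an estimated correlation), but not without spleen 3 (0.0549) or by fry (0.0673). The inhibitory receptor genes Lag3 (1.17) and Ctla4 (0.59) rose among the 25 effector and inhibitory receptor genes, of which 3 rose and 5 fell with the block. With 1 array left out in turn, Lag3 lost its call in 6 settings and Ctla4 in 8. Lag3 read 1.31 to 1.65 log2 in DMSO cultures, close to the background level of 1.23. None of the 15 naive and memory genes passed (2 rose with the block). The effector and naive lists were not called (camera adjusted p = 0.568 and 0.174). No B cell, CD4 T cell or myeloid marker passed (1 CD4 T cell marker fell with the block). Lat (-0.39), a T cell receptor adaptor gene, fell among the 13 CD8 identity genes, of which 1 rose and 3 fell with the block. None of these 4 lists was called (camera adjusted p from 0.266 to 0.812).

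Of the 24 mitosis genes 17 rose, none fell and 7 did not pass, and 23 rose when adjusted over the list alone (median 0.56, camera adjusted p = 1.72e-19). They included Cenpf (0.95) and Mki67 (0.56), a gene for a marker of cycling cells; Aspm (1.08) and Depdc1b (0.99) rose outside the list. Of the 26 DNA replication genes 6 rose, or 18 when adjusted over the list alone, with Pola1 at 0.71, Gins1 at 0.66 and Mcm6 at 0.58 (median 0.35, camera adjusted p = 8.99e-11). With an estimated correlation the adjusted p was 0.179 for mitosis and 0.200 for DNA replication. Ppat (0.54, with 1 of 2 probe sets going the other way) and Paics (0.41), which encode purine synthesis enzymes, rose among 18 (median 0.26), Rps6 (0.40) rose among the 21 ribosomal protein genes (median 0.10), and no ribosome biogenesis gene of 25 passed (median 0.13; 5 rose with the block). These 3 lists were called upward (camera adjusted p = 0.00171, 0.00300 and 0.00171; adjusted p = 0.281, 0.281 and 0.373 with an estimated correlation).

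The interferon response list of 19 genes was called downward (median -0.30, camera adjusted p = 0.00669, adjusted p = 0.393 with an estimated correlation), with Mx1 at least 1.47-fold lower and Gbp2 (0.88) higher. Cdkn1a (-0.87), Hmox1 (-0.59) and Bcl2l1 (-0.42) fell among 14 apoptosis and p53 target genes. That list was called (camera adjusted p = 0.0188, adjusted p = 0.281 with an estimated correlation), but not without DMSO replicate 2 (0.0977), KU-0063794 replicate 1 (0.0526) or spleen 2 (0.205). The sestrin genes Sesn1 (-0.67, with 1 of 4 probe sets going the other way) and Sesn3 (-1.12) fell and Ccng2 (0.68) rose among 20 FOXO targets. Eif4ebp1 (-1.08) and Sgk1 (-0.69) fell among 27 PI3K and mTOR pathway genes, Ctsd (-0.95) and Atp6v0d1 (-0.50) among 27 lysosome and autophagy genes, and Itgav (-0.88, with 1 of 3 probe sets going the other way) among 19 chemokine receptor and adhesion genes. These lists, and those of oxidative phosphorylation, the unfolded protein response and the pentose phosphate pathway, in which no gene passed, were not called (camera adjusted p from 0.105 to 0.586). With the block 2 genes rose and 2 fell in each of the last 2. Without DMSO replicate 1 the oxidative phosphorylation and lysosome lists were called (both 0.0454). With the block 3 FOXO targets rose and 2 fell, and 3 chemokine receptor and adhesion genes rose and 4 fell. Outside the lists the adhesion molecule gene Icam2 rose from 3.74 ± 0.67 to 5.24 ± 0.34 log2, Igfbp4 (1.28) and Crip1 (1.10) rose as well, and Niban1 (-2.08), Afp (-2.07) and Tmem40 (-1.95) fell.

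KU-0063794 changed 540 of 13278 genes at an adjusted p under 0.05 in limma, 303 higher and 237 lower, and 62 by at least 2-fold, 6 higher and 56 lower. The count at 2-fold was 104 with the spleen as a block, 28 without DMSO replicate 1 and 31, 32 and 27 without KU-0063794 replicates 1, 2 and 3. With the spleen as a block 1644 genes differed, 866 higher and 778 lower, and all 540 were among them. The count of all genes called was 138 without DMSO replicate 1 and 126, 129 and 120 without KU-0063794 replicates 1, 2 and 3. Of the 69 genes past the test that the naming rule took, 52 lost their call without at least 1 array and 17 kept it throughout, among them Gzmg, Ifng, Asns, Trib3, Mvd, Aldoc, Lta, Il1r2, Aspm, Crip1, Afp and Tmem40. Over the 9 left-out arrays 0 to 16 mitosis genes, 3 to 12 ATF4 targets, 1 to 9 sterol genes, 1 to 4 glycolysis genes and 0 to 7 DNA replication genes passed, the counts being lowest without DMSO replicate 1 or a KU-0063794 array.

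**Figure D2:**
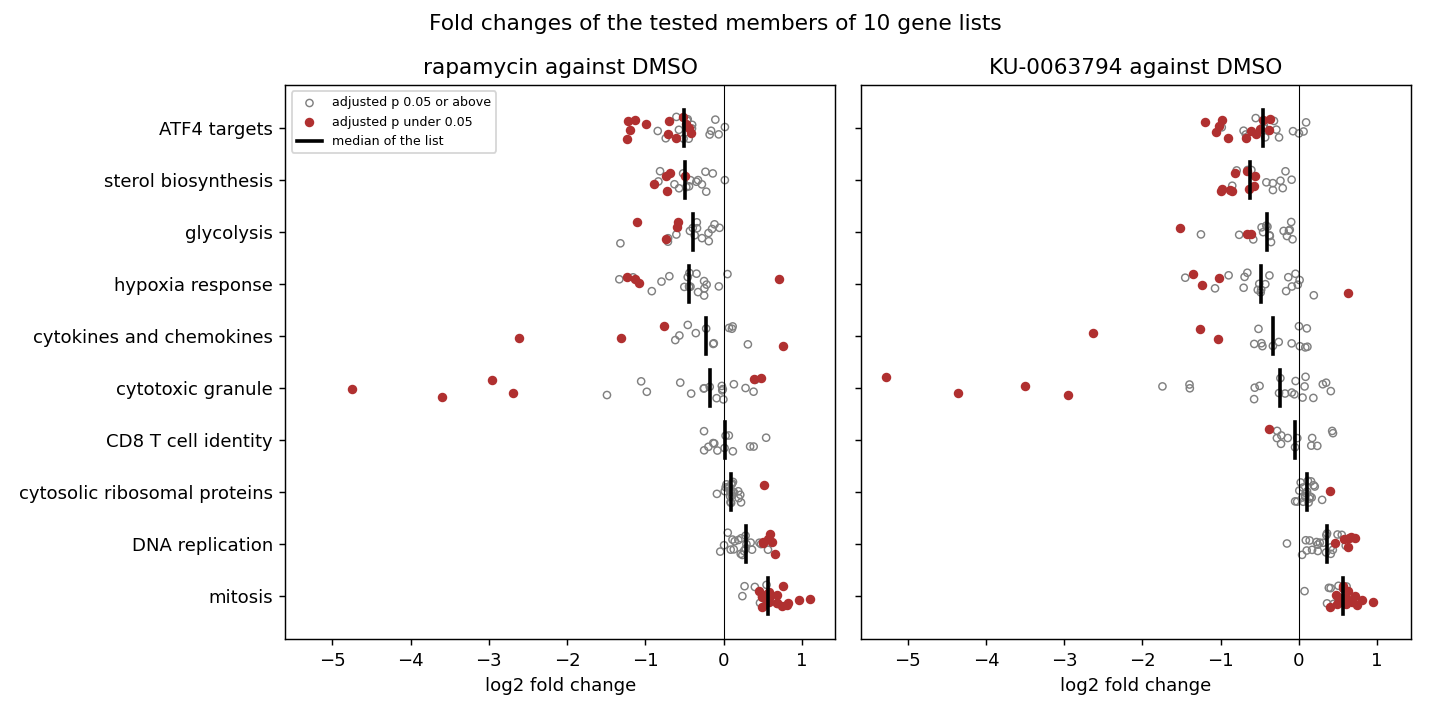
Log2 fold changes against DMSO of the tested members of 10 gene lists with rapamycin and with KU-0063794; each point is a gene, red points passed the test adjusted over all genes and black bars are list medians. The mitosis medians are 0.57 and 0.56, and the ATF4 target medians -0.51 and -0.46.

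The responses to the 2 inhibitors were then set side by side. Gzmg, Ifng, Asns, Lta, Il1r2 and Ddit4 fell and Kdm3a and Aspm rose with both drugs. In all, 390 genes were called with both inhibitors in the same direction, 225 higher and 165 lower, and no gene was called with both in opposite directions, against 1 with the spleen as a block. Independent lists of these sizes would share 8.03 higher and 4.25 lower genes, which leaves the shared DMSO arrays out and so is not the value without effects. Of all 13278 genes 76.1% had the same sign with both drugs, against 66.7% in simulations in which only the DMSO arrays were shared. Across all genes, which are not independent replicates, the log2 fold changes correlated with r = 0.851, against 0.501 in these simulations. Their covariance was 0.0606, against 0.010 in the simulations, a difference of 0.0506; simulated with the spleen as a block it was 0.00543, a difference of 0.0552. The 3 DMSO arrays were too few to give each contrast at least 2 of its own, so part of the excess of shared calls over independent lists may come from them. The shared count was 1099 with the spleen as a block, 93 without DMSO replicate 1, 245 without DMSO replicate 3, 173, 212 and 146 without rapamycin replicates 1, 2 and 3, and 104, 110 and 100 without KU-0063794 replicates 1, 2 and 3.

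**Figure D3:**
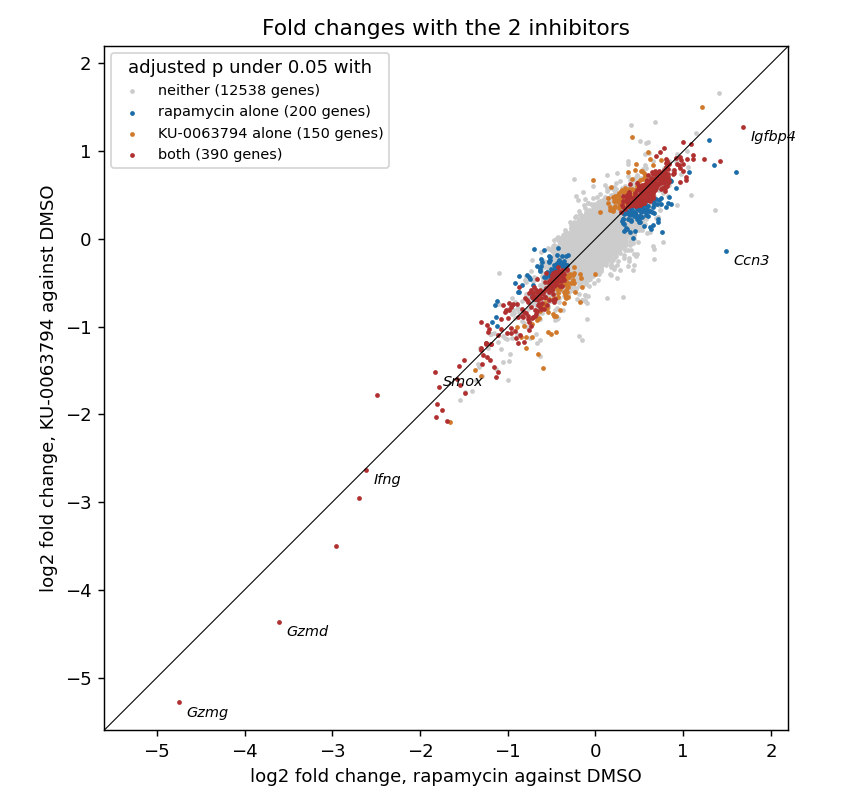
Log2 fold change against DMSO with KU-0063794 (vertical) and with rapamycin (horizontal) for the 13278 genes tested, coloured by the contrasts in which they passed; the line marks equal change. The 390 genes called with both drugs lie along the line, with Ifng at -2.62 and -2.63.

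The direct comparison of KU-0063794 with rapamycin asked which transcripts respond differently to the 2 drugs, which were given at different doses. No single gene passed the test. Ifng differed by -0.02 log2 (95% confidence interval -0.89 to 0.85), Asns by 0.19 (-0.08 to 0.47) and Mki67 by 0.09 (-0.18 to 0.37). Pdcd4 (-0.41), Ccr7 (-0.54) and Klf2 (0.47) had the same sign in all 3 spleens, with an adjusted p of 0.933 each without the block. These intervals and p-values come from limma without the block, which leaves the spread between spleens in the error. They therefore do not show that the drugs act alike on these genes, although none of them passed with the block either. The lowest adjusted p with the spleen as a block, 0.0587, belonged to Fgl2 (-0.78), Mxd1 (-0.99) and Ccn3 (-1.62). These 3 genes were chosen after their values were seen; Ccn3 had a log2 fold change of 1.49 against DMSO with rapamycin and -0.13 with KU-0063794.

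Several gene lists were called. The interferon response genes were lower with KU-0063794 than with rapamycin (median -0.39, camera adjusted p = 1.12e-07, adjusted p = 0.371 with an estimated correlation), although no member passed singly. Lysosome and autophagy genes were also lower (median -0.12, camera adjusted p = 0.000543, adjusted p = 0.113 with an estimated correlation), and neither call was lost without any 1 array. Ribosome biogenesis (median 0.12, camera adjusted p = 0.000543) and purine and one-carbon genes (median 0.15, camera adjusted p = 0.00932) were higher, each with adjusted p = 0.499 with an estimated correlation. The sterol (median -0.10), granule (-0.16), cytokine (-0.06), cytokine receptor (-0.10) and mitosis (-0.07) lists were lower, with camera adjusted p from 0.0165 to 0.0423 and adjusted p from 0.371 to 0.738 with an estimated correlation. The unfolded protein response (0.11) and effector (0.07) lists were higher (camera adjusted p = 0.0165 and 0.0462), each with adjusted p = 0.371 with an estimated correlation. Each of these last 9 calls was lost without at least 1 array, that of ribosome biogenesis without KU-0063794 replicate 2 (0.0927). With the spleen as a block the mitosis and effector calls were lost (adjusted p = 0.0641 and 0.0938) and the FOXO targets were called (0.0421, against 0.0975 without the block; adjusted p = 0.274 with an estimated correlation as well). The remaining lists, those of glycolysis, hypoxia, ATF4 targets and DNA replication among them, were not called (camera adjusted p from 0.157 to 0.975), except the ATF4 targets without rapamycin replicate 1 (0.0198) or KU-0063794 replicate 3 (0.0144). The FOXO targets were also called without rapamycin replicate 2 (0.0424), KU-0063794 replicate 3 (0.0468) or spleen 3 (0.0473).

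In limma 0 of 13278 genes passed, and the lowest adjusted p was 0.854. The unadjusted p was under 0.05 for 629 genes without the spleen as a block and for 1329 with it. Without any difference 663.9 are expected. The fit without the block leaves the spread between spleens in its error, so its count alone does not show that the drugs act alike. With the block 0 genes passed, or 1 without DMSO replicate 1 as well. The genes called against DMSO with either drug were 740. For 717 of these the 95% confidence interval of the difference between the drugs lay within 1 log2 unit of 0. The median half-width was 0.24. That margin is wider than the median absolute change of the genes called, 0.59 for each drug. A gene moved by 1 drug only could thus lie within it. In limma 111 of the 740 had an unadjusted p under 0.05, or 169 with the spleen as a block. Of 28 lists 11 were called, 4 higher and 7 lower, but 4 without rapamycin replicate 1, 7 without rapamycin replicate 3 and 2 without KU-0063794 replicate 2; fry, which tests whether the genes of a list move one way, called only the cytokine list (adjusted p = 0.0214).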

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

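Set tests with the spleen block, set tests with arrays or spleens left out and the spleen block with arrays left out were chosen only after the results were seen; all other settings were fixed before. With the spleen as a fixed block the counts were 1561 genes for rapamycin, 1644 for KU-0063794 and 1099 for the response shared by both, and with the spleen as a random effect (consensus correlation 0.254) 1245, 1291 and 859; taking the spread between spleens out of the error is how these settings are built. Fits of only the 2 groups compared, with fewer arrays behind the estimate of spread, gave 98, 111 and 56. Without 1 array or 1 spleen the counts ran from 0 to 511 for rapamycin, 0 to 540 for KU-0063794 and 0 to 354 for the shared response; without spleen 1 they were 1, 3 and 1, and without spleen 2 or 3 0 in each case. With the block and without spleen 1, 2 or 3, rapamycin gave 6, 425 and 18 genes and KU-0063794 88, 485 and 120. Quantile normalization, median centring, the filters, the other ways to take probe sets, and the trend, robust and weighted fits kept the counts of genes called against DMSO within 1.5 times, from 517 to 705 for rapamycin and 447 to 658 for KU-0063794; with the mean over probe sets the counts at 2-fold went from 63 to 37 and from 62 to 35. Centring on the tested genes moved the share of calls that were higher from 59.7% to 50.5% for rapamycin and from 56.1% to 50.3% for KU-0063794. Genes called for KU-0063794 against rapamycin stayed at 0 in every setting except the block without DMSO replicate 1, which gave 1. Pseudocounts were not run, since the values were already log2.

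With an estimated inter-gene correlation, without or with the block, 0 lists were called in any contrast. The lowest camera adjusted p without the block was 0.219, 0.163 and 0.113. Lists with an estimated correlation below the preset 0.01 lost their calls as well, among them cytokines (-0.0647) and, between the inhibitors, lysosome genes (-0.00256). The loss of calls in this setting therefore cannot be put down to correlated genes alone. Fry called 11 and 11 lists against DMSO, 10 and 9 of them also called by camera, but 1 for KU-0063794 against rapamycin, or 16, 17 and 3 with the block. Without the block it did not call hypoxia (adjusted p = 0.0617 and 0.0996) and called the naive and memory list (0.00955 and 0.0119) against DMSO. For KU-0063794 it did not call fatty acid synthesis and cytokine receptors (both 0.0673), ribosome biogenesis (0.0996), granule (0.128) and interferon response (0.253) genes either, and called chemokine receptors (0.0463); fry asks whether a list moves, not whether it moves more than other genes. Between the inhibitors the lists called ran from 2 to 11 with 1 array or spleen left out, 7 without spleen 2. The ATF4, sterol, glycolysis, hypoxia, mitosis, DNA replication and ribosomal protein calls against DMSO held for both drugs without any array or spleen, with the block and without the filter; without the filter the cytokine list lost its call for rapamycin (adjusted p = 0.0556), as the cytokine and effector lists did between the inhibitors (both 0.0541). Median, mean and test of a list differed in sign only in lists that camera did not call, among them chemokine receptors and adhesion and the CD8 identity, B cell and myeloid markers.

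Of 135 calls of named genes, 0 were lost and 16 gained with the block, 0 lost and 1 gained after quantile normalization, 26 lost with the mean over probe sets, and 99 lost without at least 1 array, most often DMSO replicate 1 (82). None reversed while past the threshold; signs of values past it in neither setting were not compared. Besides the calls given with the results, the block brought a few more genes past the threshold. Ldha (-0.39 with rapamycin and -0.38 with KU-0063794) was lower and Myc (0.48 and 0.39) higher with both drugs. Hmgcs1 (-0.81) was lower and Mki67 (0.47) higher with rapamycin, and Pdcd4 (0.41) was higher with KU-0063794. The block changed no other call of a named gene or camera call of a list. Background limits Acss2, Acvrl1, Lockd and S1pr1, and with KU-0063794 Gzmg and Mx1. Their dimmer group was at background on all 3 arrays, so only folds given as at least a value are lower bounds.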

Other observations

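The tests of CD8 identity genes, of the correlation among interferon response genes and of the control probe sets were chosen only after the result was seen, and the list of genes induced by interferon gamma was written after the data were seen, before its values were computed.

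Interferon gamma transcripts and the transcripts that interferon gamma induces did not move together. Ifng fell with both inhibitors, yet Gbp2, a GTPase gene induced by interferon gamma, rose with both (log2 fold change 1.42 with rapamycin and 0.88 with KU-0063794). Of 27 genes that interferon gamma induces 21 were tested, and only Gbp2 passed with either drug. Their median was 0.27 with rapamycin (camera p = 4.84e-07, or 0.0757 with an estimated correlation) and 0.10 with KU-0063794 (camera p = 0.365). In the 3 spleens the medians were 0.49, 0.21 and 0.24 with rapamycin and 0.20, 0.10 and -0.08 with KU-0063794. A lower output of genes induced by interferon gamma was taken to need medians below -0.1; the lower of the medians, 0.10, lay above that by more than the spread between spleens (SD 0.14), which argues against it. Interferon gamma still present in the cultures may have kept these genes up; this was not tested, and protein levels were not analysed here.

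Mitosis genes were higher with both inhibitors, with medians of 0.57 and 0.56. A trend of the normalization with signal level would also lift other genes of the same brightness, but the medians lay above those of all 10000 random lists matched for signal, at the percentile of 100, the highest random medians being 0.20 and 0.23. Fewer cells without T cell genes in treated cultures would raise the genes of the CD8 T cell identity list alike. The medians of its 13 genes were 0.0129 (SD 0.25) and -0.05 (SD 0.28), further below the mitosis medians than their spread. Most of these genes are shared by T cells in general, so the list cannot tell about fewer T cells of other kinds. Cd8b1 read 7.23 log2 in DMSO, 7.62 in rapamycin and 7.47 in KU-0063794 cultures, and Cd8a 6.55, 6.56 and 6.41. A larger share of dividing cells and a shift of the remaining cells through the cycle may both be behind the change; cell counts and DNA content were not analysed here.

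The interferon response list was lower with KU-0063794 than with rapamycin, with a median of -0.39. Within spleens 1, 2 and 3 the median differences were -0.61, -0.16 and -0.16, with 19, 15 and 13 of 19 genes lower, so a difference carried by spleen 1 and one present in all 3 cannot be told apart at this spread. With an estimated correlation of 0.387 the camera adjusted p was 0.371. That setting called no list in any contrast, also not the lysosome and autophagy list, whose estimated correlation was -0.00256. Whether correlation among the genes explains the low camera p therefore cannot be told from it. The 21 genes induced by interferon gamma also had a lower median with KU-0063794 than with rapamycin, -0.25. Their unadjusted p was 0.0310 in camera with an estimated correlation and 0.0586 with the block as well. Unlike the adjusted p of 0.371, these values cover 1 list alone, written after the data were seen, so they cannot be compared with it. Gbp2 is a member of both lists. A biological difference between the inhibitors, which were given at different doses, stays open.

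The B1 repeat control probe set was lower with both inhibitors, with log2 changes of -1.07 with rapamycin and -0.80 with KU-0063794 (SE 0.25). Lower signal of control probe sets in general was argued against by the other 61, whose medians were -0.07 and -0.14 (SD 0.13 and 0.17). The B2 repeat probe set that was not near the top of the scale changed by -0.24 and -0.20 (SE 0.07), in the same direction as B1, so a loss of short repeat transcripts in general and one of B1 alone cannot be told apart from 1 probe set. Fewer repeats carried in other transcripts may contribute and was not tested.

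For 3 arrays against 3 the 10 splits of the 6 arrays are too few for a share under 0.05. The real split called 590 genes for rapamycin, 540 for KU-0063794 and 0 for KU-0063794 against rapamycin, and the highest of the other splits called 0 in each, so that 1, 1 and 10 of the 10 splits gave as many. For the lists the real split called 11, 15 and 11 and the highest other 13, 12 and 9, so that 2, 1 and 1 splits gave as many. Of the splits that part all 3 spleens, as the real one does, the others called at most 0 genes and 7, 8 and 1 lists. Of 100 assignments of the 9 arrays to 3 groups, 2 gave at least the 390 genes called with both inhibitors, the real one included. The other gave 426. It kept the 3 DMSO arrays together and mixed the arrays of the 2 inhibitors. Of 100 assignments within spleens only the real one gave as many, 390 against at most 340 in the others. With the spleen as a block these counts were 1099 and 913. For the genes called with both inhibitors, the shares of the 100 assignments argue against a chance parting of the DMSO arrays from the treated ones. These shares cannot tell how alike the 2 inhibitors are. The 10 splits decide nothing by themselves. Since mixed groups also gave up to 13 and 12 list calls against DMSO, the low camera p at the preset correlation overstates the evidence for single lists.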
